A study of Mus musculus with 2 samples.

How the data were processed

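The study compared tumours of the ID8 mouse model of ovarian cancer before and after cisplatin by single-cell RNA sequencing. ID8 is a line derived from C57BL/6 mouse ovarian surface epithelium that forms tumours in the peritoneal cavity of immunocompetent mice. The labels describe 2 libraries, 1 of treatment-naive primary tumours and 1 of chemoresistant tumours exposed to cisplatin. Per the labels' protocols, fresh tumour tissue was minced, digested with collagenase, filtered and freed of red cells by lysis. Suspensions of several tumours were pooled before loading on a Chromium chip with 3' v3 chemistry. The number of tumours per pool is not given in the sources used here. Because each group is 1 pooled library, no animal can be separated from another and the difference between groups has no replicate check.

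The deposited matrices hold whole-number UMI counts per gene and barcode that the authors made with Cell Ranger 8.0.1, per the file headers and the submitters' processing notes. The genome build was mm10 per the submitters' processing notes, and the annotation version is not given in the sources used here. Barcodes in the matrices all had at least 500 UMIs. Gene symbols and identifiers were taken as the files pair them. A few older symbols in the gene lists (Tcrg-C1, Tcrg-C2, Cd163l1, Ddx58 and Ero1l, now Trgc1, Trgc2, Scart1, Rigi and Ero1a) were matched through the names of the reference annotation, while Bim, Cd39 and Ctgf were not found. For the analysis by chromosome, the GENCODE vM21 annotation gave a chromosome for 31961 genes and none for 1735, and no coordinates were used.

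The primary library held 14390 barcodes and 141334623 UMIs, and the chemoresistant library 16390 barcodes and 158118781 UMIs. Barcodes were kept with at least 500 UMIs, at least 250 detected genes and at most 20% mitochondrial UMIs. The mitochondrial limit removed 1483 barcodes (10.3%) of the primary library and 427 (2.61%) of the chemoresistant library, and the gene limit 287 and 1085. This left 12824 and 14908 barcodes. Doublets were called per library with Scrublet as built into scanpy 1.11.5, with an expected rate of 0.08. The automatic threshold marked 297 primary barcodes (2.32%) but 0 chemoresistant barcodes. The fallback fixed for a share under 0.5%, which sets the share to 0.8% per 1000 barcodes, was therefore used for the chemoresistant library and removed 1886 barcodes (12.7%). Doublet removal was thus stricter in the chemoresistant library, and an alternative chosen after seeing the data set the same share rule for both, which called 1460 primary barcodes (11.4%) and left 11364. The main comparison used 12527 primary and 13022 chemoresistant cells, with a median of 5628 and 4099.5 UMIs and 2267 and 1746 genes per cell.

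Counts were scaled to 10000 per cell and log-transformed, and both libraries were clustered together on 2000 variable genes, 30 principal components and 15 neighbours with the Leiden algorithm (leidenalg 0.10.2) at resolution 1.0. No batch integration was applied. The 42 clusters were named from marker lists fixed with the other design choices before the data were examined. How a list turns into a name was set after seeing the marker tables. A marker counted when it lay over 1 on the log2 scale above the median cluster (20 CPM added) and was detected in at least 20% of cells. A name needed at least 3 such markers, and no other class could have more markers among the 10 leading genes. Clusters with at least 80% and at least 5 of the markers of another class, or at least 3 of its markers among the leading genes, were set aside as carrying markers of 2 classes. The set-aside clusters (24, 29, 34 and 38) made up 3.81% of primary and 1.51% of chemoresistant cells, and the unnamed ones (26 and 36) 2.27% and 0.0230%. Each of the 8 tumour clusters carried 4 to 11 of the 16 tumour epithelial and 3 to 7 of the 8 mesothelial markers, so that the lists did not part them and they form 1 tumour class. B cells and plasma cells form 1 B-lineage class because cluster 15 held both. A further rule, which would have taken out non-leukocyte clusters whose chromosome profile correlated with the tumour class above 0.8, was tried and dropped. The collagen-rich cluster 20 came out at 0.758 at the main settings and at 0.830 with doublets kept, so the outcome would have depended on where the limit was set. Cluster 20 is therefore a fibroblast cluster by its markers, and its count as tumour is an alternative chosen after seeing the data. T cells were clustered again alone on 20 components into 19 clusters. A regulatory T name was given only where Foxp3 was detected in at least 20% of cells, a condition added after a cluster led by Ifng and Il17a without Foxp3 had first taken that name.

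Shares of cells carry exact Clopper-Pearson 95% intervals. For each class with at least 100 cells in both libraries, raw counts were summed per library and expressed as CPM, counts scaled to a total of 1e6, with exact Poisson 95% intervals. All intervals cover counting error only, not differences between animals, pools or days. Log2 ratios are chemoresistant over primary with 5 CPM added to both, which understates changes of low genes, and folds are on the same scale. Where a library had 0 counts, the fold is a lower bound against a floor of 3 counts per library and class. Each gene list fixed in advance was summarised by the median log2 ratio of members with at least 10 CPM in 1 library. The percentile of that median among 10000 random lists of the same size and matched mean expression describes these 2 libraries and is not a test. A member counted as higher or lower at 1.5-fold. With 1 library per group no p-value, standard error or number of changed genes was computed.

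Genes were named by a fixed rule: at least 30 CPM in 1 library, detection in at least 5% of the class there, and at least 10% of the highest level in any other class of at least 50 cells. The 12 highest and 12 lowest were taken in tumour cells, 8 each way in mononuclear phagocytes and T cells, and 3 each way in fibroblasts, beside the 2 highest and 2 lowest members of each list and 8 classic targets. List members and classic targets were not held to the 10% limit, so those far higher in another class are open to free RNA. Mitochondrial, ribosomal-protein, haemoglobin and receptor-segment genes and uncharacterised transcripts were left out. A few list members that the rule takes are not reported here. The steps were tested on simulated data for each class, with 100 genes raised and 100 lowered 2-fold. Median recovered log2 ratios were 0.997 and -0.988 in the tumour simulation (8803 genes), 0.998 and -0.982 for mononuclear phagocytes (8291 genes), 0.982 and -1.02 for T cells (8670 genes) and 1.01 and -0.968 for fibroblasts (8687 genes). These medians were computed with a smaller amount added than the 5 CPM of the reported ratios, and corrected for the known shift in totals. They therefore do not show how closely the reported ratios recover a change. For the lists, 5 CPM were added without that correction. In each simulation all 20 raised lists lay at or above the 97.5 percentile. Of 20 unchanged lists, 0, 2, 0 and 2 fell outside the 2.5 to 97.5 percentiles.

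Alternatives fixed in advance were a stricter filter (1000 UMIs, 500 genes, 10% mitochondrial UMIs), the 10% mitochondrial limit alone, doublets kept, resolution 2.0, a class per cell from its highest marker score, shares outside the tumour class, a pseudocount of 1 CPM, centring on the median of all genes with at least 10 CPM, the mean over cells scaled to 1 total, thinning to 2000 UMIs per cell, subtraction of 5% free RNA, no filter on list members, tumour cells without Mki67, Top2a or Cdk1 counts, and T subsets from detected transcripts. Those chosen after seeing the data were the same doublet share in both libraries, cluster 20 as tumour, tumour cells without clusters 13 and 30, and the mean over the 6 tumour clusters with at least 50 cells in both libraries. The endothelial class had under 100 cells in the chemoresistant library, so its expression was not compared. Analyses ran in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and Matplotlib 3.10.9.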

Results

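Single-cell transcriptomes were obtained from solid tumours of mice carrying ID8 ovarian cancer, either treatment naive (primary) or exposed to cisplatin, a platinum drug that crosslinks DNA, and described as chemoresistant. Each group was 1 library made from pooled tumours. The primary library contributed 12527 cells at a median of 5628 UMIs per cell and the chemoresistant library 13022 cells at 4099.5 UMIs. No value below has a replicate, and the intervals given are 95% intervals of counting error.

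The first comparison asked how the cellular make-up of the tumours differed. Tumour cells made up 10.0% of the primary library (1253 cells, interval 9.48 to 10.5%) and 26.2% of the chemoresistant library (3406 cells, 25.4 to 26.9%). Mononuclear phagocytes, that is monocytes and macrophages, were 24.4% (23.7 to 25.2%) and 31.1% (30.3 to 31.9%), a difference of 6.61 percentage points that was 14.9 among cells outside the tumour class. T cells fell from 8.65% (8.17 to 9.16%) to 2.35% (2.10 to 2.62%), and neutrophils from 12.8% (12.2 to 13.4%) to 5.56% (5.17 to 5.97%). Endothelial cells, which line blood vessels, went from 140 cells (1.12%, 0.941 to 1.32%) to 7 cells (0.0538%, 0.0216 to 0.111%). Adipocytes numbered 47 in the primary library (0.375%) and 0 in the chemoresistant library, which allows a share of up to 0.0230% (3 cells taken as the limit of a count of 0). Cluster 26, with the intestinal gene Fabp2 among its leading genes, held 235 primary and 3 chemoresistant cells. Differences in share may therefore not be those of tumour tissue alone, which was not tested.

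**Figure D1:**
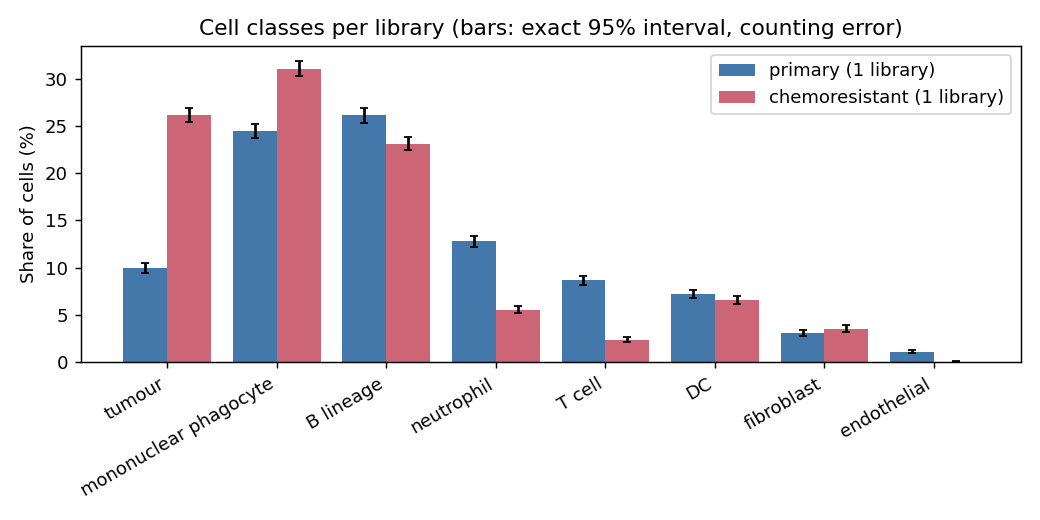
Share of cells (%, vertical axis) in each of 8 classes (horizontal axis) for the primary and the chemoresistant library, 1 library each, with bars for the exact 95% interval of counting error. The tumour share stands at 10.0% and 26.2%, and the T-cell share at 8.65% and 2.35%.

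Dendritic cells, which present antigen to T cells, stood at 7.20% (6.75 to 7.67%) and 6.55% (6.13 to 6.99%). B-lineage cells were 26.1% (25.4 to 26.9%) of the primary and 23.1% (22.4 to 23.9%) of the chemoresistant library. As shares of the cells outside the tumour class, both went the other way, by 0.870 and 2.30 percentage points in favour of the chemoresistant library. Fibroblasts were 3.11% (2.82 to 3.43%) and 3.56% (3.25 to 3.90%), a difference of 0.450 percentage points that depended on the setting. It was 2.98 with doublets kept, 1.77 with the stricter filter, 1.37 outside the tumour class, 1.17 with the same doublet share in both libraries and -3.06 with cluster 20 counted as tumour. The set-aside cluster 24, with 10 of 11 fibroblast and 8 of 8 mesothelial markers, held 1.85% of primary and 0.361% of chemoresistant cells. Counted as fibroblasts, its cells would make the fibroblast share lower in the chemoresistant library. Mast cells or basophils were 16 and 7 cells.

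Several classes rested on different clusters in the 2 libraries. Cluster 8 held 49.5% of the primary tumour cells and 7.72% of the chemoresistant ones, while cluster 5 held 11.7% and 36.5%. Clusters 14, 18 and 25 together with cluster 5 held most chemoresistant tumour cells, with 499, 458 and 256 cells against 68, 19 and 2 in the primary library. Among B-lineage cells, cluster 2 held 56.8% of the primary and 3.85% of the chemoresistant cells and cluster 0 held 6.69% and 80.1%. Primary fibroblasts lay in clusters 27 (234 of 390) and 32 (154), and 459 of the 464 chemoresistant fibroblasts in cluster 20. Median depth also differed within classes, for example 4879 and 1653.5 UMIs in T cells and 2415.5 and 892.5 in neutrophils, and doublet removal took 2.32% of primary and 12.7% of chemoresistant barcodes, so shares of shallow classes can move with the limits on barcodes.

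Among the T cells, CD4 T clusters held 20.8% of primary cells (225 of 1084, 18.4 to 23.3%) and 16.3% of chemoresistant cells (50 of 306, 12.4 to 21.0%), and the call from transcripts gave 33.0% (30.2 to 35.9%) and 23.9% (19.2 to 29.04%). Regulatory T cells, marked by the transcription factor Foxp3 in 49.3% of the cells of their cluster, were 4.70% (3.52 to 6.14%) and 5.88% (3.52 to 9.14%), a difference within counting error. Called from transcripts in each cell, regulatory T cells were 3.87% (2.81 to 5.20%) and 1.31% (0.357 to 3.31%), the opposite direction by -2.57 percentage points. The cluster named gamma delta T held 61 primary cells (5.63%, 4.33 to 7.17%) and 0 chemoresistant cells, but the call from transcripts gave 127 (11.7%, 9.86 to 13.8%) and 8 (2.61%, 1.14 to 5.09%). Natural killer cells were 46 and 4 cells and type 2 innate lymphoid cells 40 and 1. The cluster named CD8 T went from 7.66% (6.14 to 9.40%) to 0.980% (0.203 to 2.84%), but 49.7% of primary and 72.9% of chemoresistant T cells stayed unnamed. Among the unnamed T-cell clusters, cluster 12 (10 and 47 cells) carried 5 of 5 CD8 T markers and clusters 5 (5 and 84 cells) and 11 (55 and 3 cells) carried 3. T-cell cluster 1 (156 and 1 cells), also unnamed, had Cd8b1 among its leading genes. At resolution 2.0 the CD8 T difference was 9.90 percentage points in favour of the chemoresistant library. Called from Cd8a or Cd8b1 transcripts instead, CD8 T cells were 18.0% (15.7 to 20.4%) and 24.2% (19.5 to 29.4%), the opposite direction. Calls from transcripts depend on depth, which was 4879 and 1653.5 UMIs per T cell.

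The second comparison asked what differed in the cancer cells. In chemoresistant tumour cells, genes of inflammatory signalling and of the immediate early response were lower. The neutrophil-attracting chemokine Cxcl1 (ENSMUSG00000029380) stood at 1196 CPM (1185 to 1206) in the primary and 70.3 CPM (68.5 to 72.2) in the chemoresistant library, a 15.9-fold difference, and Cxcl1 was also a leading gene of cluster 8. Irf1 (ENSMUSG00000018899), a transcription factor of the interferon response, went from 496 (489 to 503) to 44.2 (42.8 to 45.7) CPM. The feedback inhibitor of NF-kB signalling Tnfaip3 went from 134 (130.3 to 137) to 12.5 (11.8 to 13.3) CPM, and Zfp36, which destabilises cytokine mRNAs, from 478 (472 to 485) to 53.2 (51.6 to 54.8) CPM. On the other side, the adhesion molecule Ncam1 (ENSMUSG00000039542) stood at 2.31 CPM (1.86 to 2.83) in the primary and 64.8 CPM (63.03 to 66.6) in the chemoresistant library, a 9.55-fold difference, and the acute-phase protein gene Saa3 went from 35.8 (33.99 to 37.7) to 290.1 (286 to 294) CPM, beside 704 to 2142 CPM in mononuclear phagocytes and 1539 CPM in primary fibroblasts. The proliferation marker Mki67 went from 59.99 (57.6 to 62.4) to 15.8 (14.9 to 16.6) CPM.

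Of 26 measured immediate early and heat shock genes, 19 were at least 1.5-fold lower and 0 higher, with a median log2 ratio of -1.49, below every one of the 10000 random lists. Ier2 (log2 -2.67) and Zfp36 (-3.05) stood lowest, and Fosl1 (0.24) and the mitochondrial chaperonin Hspe1 (0.13) highest. The same list had medians of -0.70 in neutrophils, -0.65 in B-lineage cells, -0.64 in T cells, -0.41 in dendritic cells and -0.080 in mononuclear phagocytes. NF-kB and inflammatory secretion genes had a median of -1.02 (percentile 0), with 14 of 22 lower and 1, Saa3, higher. Complement C3 stood at log2 0.53. Stem-associated genes had a median of -0.72 (percentile 0.0100), which was -0.12 with no filter on list members, with 7 of 12 lower, among them Myc (153 to 42.4 CPM) and Lgr5 (36.7 to 10.3 CPM), and 1 higher, the hyaluronan receptor Cd44 (42.9 to 71.7 CPM). Neutrophils of the 2 libraries held 670 and 673 CPM of Cd44, so its counts in primary tumour cells are open to free RNA.

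Genes of mitosis had a lower median in chemoresistant tumour cells, though 12 of 23 lay within 1.5-fold. The G2 and M list had a median of -0.58 (percentile 0), with 11 of 23 lower and 0 higher, from Birc5 at -0.07 and Ube2c at -0.18 to the kinetochore gene Cenpf at -1.43 and Mki67 at -1.65. The median was -0.20 when cells with a count of Mki67, Top2a or Cdk1 were left out. It was -0.21 as a mean over the 6 clusters shared by both libraries, an alternative chosen after seeing the data. The median of all genes with at least 10 CPM was -0.13. Mki67 was also the lowest member of the G2 and M list in mononuclear phagocytes (-1.14) and fibroblasts (-0.35), though not in T cells. Fewer dividing cells and differences in single transcripts were not told apart. S phase genes had a median of -0.31 (percentile 3.21), with 3 of 19 lower, among them Hells (-0.86) and Rrm1 (-0.67), while Dut (0.36) and Tipin (0.16) stood highest.

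Genes of the response to platinum differed little as groups. Targets of p53, the transcription factor activated by DNA damage, had a median of 0.0024 (percentile 91.4), with 3 of 25 higher and 7 lower, and its sign changed under 7 of 13 alternatives (-0.10 to 0.13). Phlda3 (log2 0.70) and Rps27l (0.69) stood highest, Fas (-1.27) and Btg2 (-2.17) lowest. The classic targets Cdkn1a and Mdm2 stood at 237 to 196 CPM and 75.7 to 62.4 CPM. DNA repair genes had a median of -0.24 (percentile 10.8), with 3 of 20 lower and 0 higher, the excision repair genes Xpa (0.44) and Ercc1 (0.29) highest, and Rev3l (-0.93) and Ercc6 (-1.10) lowest. Platinum and drug transport genes had a median of 0.094 (percentile 95.8). The copper chaperone Atox1, which also binds platinum, went from 408 (402 to 415) to 681 (675 to 687) CPM, and the efflux pump Abcc1 from 118 (115 to 122) to 54.02 (52.4 to 55.6) CPM, the single members past 1.5-fold each way, with Abcc3 at log2 0.47 and Atp7a at -0.43. The copper importer Slc31a1 stood at 26.4 (24.9 to 28.1) to 28.7 (27.6 to 29.9) CPM, Abcb1b at 8.51 to 10.7 CPM and Abcb1a at 1.84 to 1.23 CPM, the last 187 CPM in primary T cells. Atp7b had 2 and 10 counts, too few for a comparison.

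Metallothionein, glutathione and NRF2 targets had a median of 0.19 (percentile 97.8), which was 0.40 after thinning and 0.064 as a mean over the 6 shared clusters, with 5 of 24 higher and 2 lower. The glutathione transferase Gsto1 went from 8.69 (7.80 to 9.65) to 72.1 (70.2 to 73.95) CPM and the peroxiredoxin Prdx1 from 835 to 1433 CPM, whereas Gstm1 went from 3808 to 1239.5 CPM and malic enzyme Me1 from 424 to 225 CPM. Hypoxia and glycolysis genes had a median of 0.30 (percentile 99.96), with 6 of 28 higher and 2 lower. The mitophagy receptor Bnip3 went from 21.4 (20.01 to 22.9) to 90.5 (88.4 to 92.6) CPM and the oxidoreductin Ero1a from 104 to 261 CPM, while Hk2 (-0.59) and Pfkl (-0.74) stood lowest. Oxidative phosphorylation genes had a median of 0.18 (percentile 86.0), with 6 of 38 higher, among them Ndufa4 (1.18) and Cox5a (0.79), and 0 lower, with Ndufs1 at -0.24 and Atp5b at -0.38. Cholesterol and fatty acid synthesis genes had a median of -0.39 (percentile 0.390), with 6 of 20 lower, among them the fatty acid synthase Fasn (-0.96), and Scd1 (0.46) and Sc5d (0.24) highest.

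**Figure D2:**
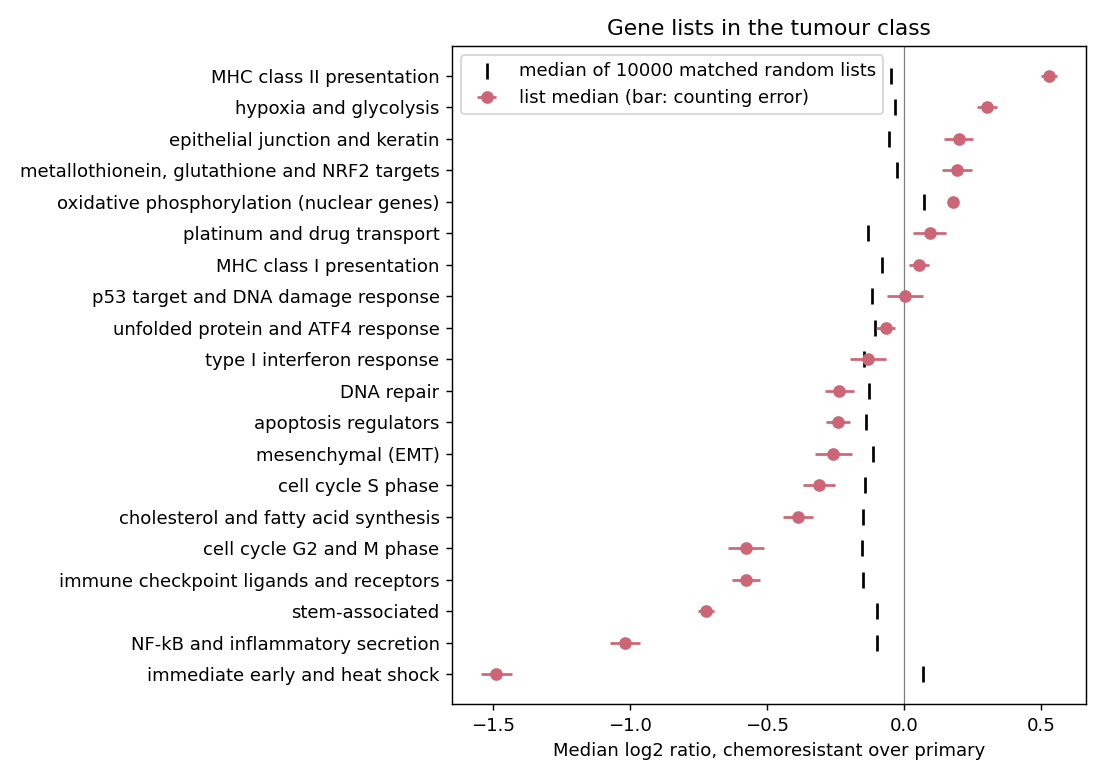
Median log2 ratio, chemoresistant over primary (horizontal axis), of 20 gene lists in the tumour class (vertical axis), with bars for counting error and black ticks for the median of 10000 matched random lists. Immediate early and heat shock genes lie lowest at -1.49 and MHC class II genes highest at 0.53, a median that was 0.077 as a mean over the 6 shared clusters.

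Genes of antigen presentation by MHC class II had a median of 0.53 (percentile 99.94), with 4 of 9 higher and 1 lower. That median was 0.26 after thinning, 0.17 as a mean over cells and 0.077 as a mean over the 6 shared clusters. H2-Aa went from 436 (429.9 to 443) to 906 (899.9 to 913) CPM and H2-DMb1 from 65.5 to 111 CPM, the class II transactivator Ciita stood at 12.6 to 13.97 CPM, and the protease Ctss went from 81.5 to 27.2 CPM. Dendritic cells of the 2 libraries held 6982 and 6695 CPM of H2-Aa and 528 and 332 CPM of Ciita. Mononuclear phagocytes held 2211 and 2090 CPM of Ctss. Tumour counts of Ciita and Ctss, and of H2-Aa in the primary library, are therefore open to free RNA. MHC class I genes had a median of 0.055 (percentile 85.8), with H2-T23 (0.62) and Psmb8 (0.49) highest and Nlrc5 (-0.38) and H2-Q7 (-0.51) lowest. It came out at -0.21 as a mean over the 6 shared clusters. Type I interferon genes had a median of -0.13 (percentile 57.5), with Zbp1 (0.95) and Rtp4 (0.77) among 2 higher and Ifit1 (-1.44) and Ifit2 (-1.59) among 7 lower of 23. It came out at -0.40 as a mean over cells, -0.39 after thinning, -0.0040 once centred and 0.057 with the same doublet share removed from both libraries. Checkpoint genes had a median of -0.58 (percentile 1.09), with 4 of 8 lower, among them the PD-1 ligand Cd274 (15.1 to 5.78 CPM) and Pvr (40.1 to 21.5 CPM), and Cd47 (0.18) and Cd24a (0.13) highest. With the same doublet share removed from both libraries that median was 0.010. Cd274 stood at 858 CPM in primary neutrophils and 215 CPM in chemoresistant dendritic cells, so its counts in tumour cells are open to free RNA.

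Epithelial junction and keratin genes had a median of 0.20 (percentile 96.7), which was 0.42 after thinning and -4.18e-05 with no filter on list members, with 2 of 12 higher, the tight junction gene Cldn3 (20.4 to 57.8 CPM) and Krt18 (517 to 791 CPM), and 2 lower, Spint2 (-0.79) and Dsg2 (-1.05). Mesenchymal genes had a median of -0.26 (percentile 6.96) that was 0.38 with cluster 20 counted as tumour, with 3 of 20 higher, led by the collagen crosslinking enzyme Lox (2.28 to 17.1 CPM) and Col6a1 (0.80), and 6 lower, among them Sparc (-0.89) and Tgfbi (-1.10). Apoptosis regulators had a median of -0.24 (percentile 12.3), with the pro-apoptotic Bad (0.65) and Bax (0.62) higher and 7 of 21 lower, among them Birc3 (-1.62) and Bcl2a1b (-1.16). Bcl2a1b stood at 32.3 and 11.8 CPM in tumour cells against 718 and 1016 CPM in mononuclear phagocytes, so its tumour counts are open to free RNA. The unfolded protein and ATF4 list had a median of -0.067 (percentile 65.2), with Ppp1r15a (-2.27) and the serine synthesis enzyme Phgdh (-1.64) as its 2 lower members of 23, and Sdf2l1 (0.47) and Sesn2 (0.33) highest. The sign of that median changed once ratios were centred and with cluster 20 counted as tumour.

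Further genes named by the fixed rule were higher in chemoresistant tumour cells: the chemokine Cxcl17 (10.4 to 69.2 CPM), Plcl1 (7.55 to 54.7 CPM), the carboxypeptidase subunit Cpn1 (3.60 to 34.4 CPM), the calcineurin regulator Rcan2 (23.5 to 116 CPM), the proteoglycan Gpc1 (13.3 to 69.96 CPM), the nicotinamide methyltransferase Nnmt (62.1 to 260.0 CPM), Mgst2 (4.64 to 32.9 CPM) and the myosin light chain Myl9 (4.79 to 30.5 CPM). Lower were the defensin Defb19 (145 to 9.22 CPM), AA467197 (421 to 40.2 CPM), the growth factor Igf1 (125 to 14.8 CPM) and Auts2 (249.6 to 38.05 CPM). Cfd, an adipocyte product at 44714 CPM in the 47 primary adipocytes, had 58.2 CPM in primary tumour cells and 0 counts in the chemoresistant ones, at least 1567-fold lower. The intestinal lipid-binding protein gene Fabp2 went from 35.6 to 0.223 CPM and stood at 16577 CPM in cluster 26 of the primary library. Camk1d went from 379 to 52.5 CPM and was lower in all 6 classes examined, by log2 -2.74 to -0.75.

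Ratios also differed by chromosome, a comparison added after the data were seen. After centring on the median gene, the 364 genes of chromosome 8 had a median of -0.24 and the 362 genes of chromosome 10 a median of -0.21 in tumour cells, each below all 10000 matched random lists, and among the 20 chromosomes chromosome 4 stood highest at 0.14. Chromosomes 2, 4, 7 and 9 lay above all random lists, with medians of 0.092, 0.14, 0.11 and 0.13. Chromosomes 3, 11 and 14 lay at or under percentile 0.05, with -0.090, -0.048 and -0.11. Chromosomes 1, 16 and 17 lay at percentiles 0.84, 1.54 and 0.89, and chromosomes 13, 15, 19 and X at 99.57 or above. The random lists therefore do not set apart chromosomes 8 and 10, which had the lowest medians of all chromosomes. Percentiles were not computed in other classes, where neutrophils reached 0.14 on chromosome 19 and -0.091 on chromosome 18.

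**Figure D3:**
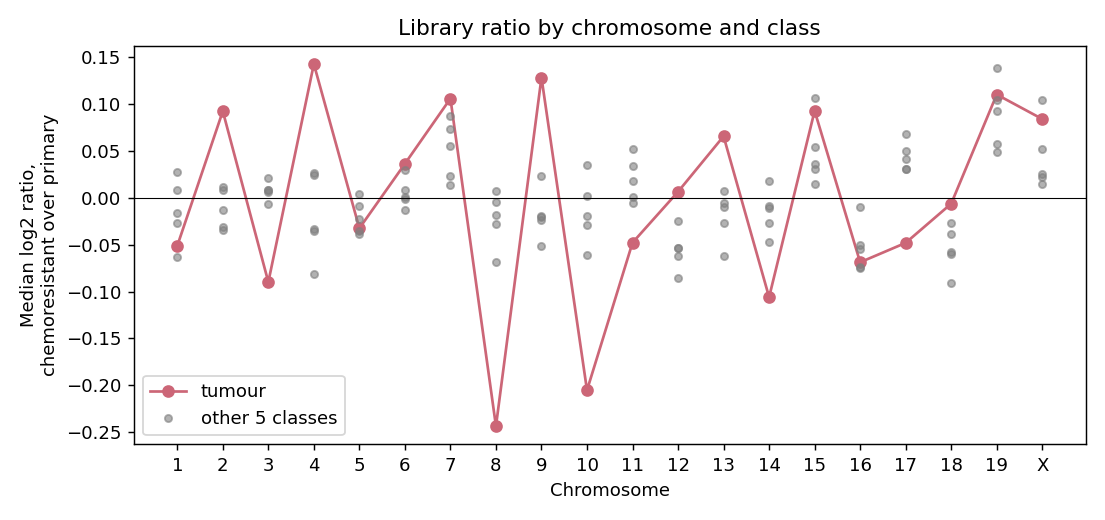
Median log2 ratio, chemoresistant over primary and centred on all genes (vertical axis), of the genes of each chromosome (horizontal axis) in tumour cells (line) and in 5 other classes (grey points), from 1 library per group. Tumour cells lie at -0.24 on chromosome 8 and -0.21 on chromosome 10, below the 5 other classes on both.

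The median of all 9285 genes with at least 10 CPM lay at -0.13 in tumour cells, and the ratios of genes and lists above are not corrected for it. As a mean over the 6 shared tumour clusters, the medians were -0.84 for immediate early and heat shock genes, -0.59 for NF-kB genes and -0.46 for stem-associated genes.

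The third comparison covered mononuclear phagocytes (3062 and 4044 cells). Single genes of scavenging were higher in the chemoresistant library, while 16 of 19 genes of complement and scavenging lay within 1.5-fold. Vsig4, a complement receptor detected in 3.76% and 4.28% of the cells, went from 10.7 (9.63 to 11.8) to 63.6 (60.5 to 66.8) CPM, the phosphatidylserine receptor Timd4 from 10.2 (9.20 to 11.3) to 21.6 (19.8 to 23.6) CPM and the lipoxygenase Alox15 from 37.04 (35.1 to 39.1) to 107 (103 to 111) CPM. Saa3 went from 704 (695 to 713) to 2142 (2123 to 2159.8) CPM and the membrane protein Ly6a from 152 (148 to 156) to 615 (605 to 625) CPM. Nos2, the inducible nitric oxide synthase, went from 38.3 (36.3 to 40.4) to 6.31 (5.36 to 7.38) CPM, and the lectin Mgl2 from 117 (113 to 121) to 43.5 (40.9 to 46.2) CPM. Cluster 7, led by Saa3, held 4.38% of the primary and 24.4% of the chemoresistant class, cluster 1 held 35.8% and 23.4%, cluster 4 held 26.1% and 22.4%, and median depth was 10908.5 and 5158 UMIs.

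The complement and scavenging list had a median of 0.30 (percentile 99.98), with 3 of 19 higher and 0 lower, and Cfp (-0.42) among the lowest. Hypoxia and glycolysis genes had a median of 0.26 (percentile 100), with 7 of 28 higher, led by Ndrg1 (1.11) and P4ha2 (0.81), and 0 lower, with Pfkfb3 at -0.40 and Pfkfb4 at -0.50. NF-kB and inflammatory secretion genes had a median of 0.13 (percentile 99.88), with 5 of 24 higher, among them Saa3 and the cytokine Il6 (7.97 to 25.9 CPM), and 2 lower, Nfkb2 (-0.64) and Lcn2 (-1.10). MHC class I genes had a median of 0.12 (percentile 99.5), with 0 of 18 past 1.5-fold, H2-K1 (0.47) and B2m (0.36) highest and H2-Q7 (-0.46) and Tap2 (-0.27) lowest. Type I interferon genes had a median of 0.066 (percentile 99.94), with 4 of 27 higher, among them Isg15 (0.80) and Oas3 (0.65), and Parp14 (-0.48) and Oas2 (-0.58) lowest. MHC class II genes had a median of -0.23 (percentile 9.61), with Ciita (-0.81) the 1 lower of 9, H2-Eb1 at -0.42, H2-DMa at 0.014 and Ctss at -0.081. That median was 0.0044 once ratios were centred, since the median of all 8614 genes lay at -0.24, and centring also turned the medians of tissue remodelling (0.12), classical activation (0.14) and immediate early genes (0.16).

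Among the other lists of this class, the lipid-associated and phagolysosomal genes had a median of 0.077 (percentile 83.1), with 4 of 24 higher, among them Syngr1 (0.95) and the apolipoprotein Apoc2 (0.94), and Nceh1 (-0.43) and Atp6v0d2 (-0.57) lowest. Tissue remodelling and alternative activation had -0.12 (percentile 55.3), with Il10 (0.80) the 1 higher of 20, Lyve1 at 0.45, and 4 lower, among them Retnla (-1.05) and Mgl2. Classical activation had -0.096 (percentile 94.7), with Il6 and Tnf (0.86) higher and Nos2 and Cd86 (-0.66) lower of 19. Checkpoint genes had -0.26 (percentile 33.8), with Cd200r1 (-0.78) and Cd86 lower of 14 and Nt5e (0.44) and Nectin2 (0.21) highest. Immediate early and heat shock genes had -0.080 (percentile 78.1), with Jun (-0.66) the 1 lower of 24, Atf3 at -0.58, Hspa1b at 0.44 and Hspa1a at 0.42. G2 and M genes had -0.42 (percentile 0.190), with 7 of 25 lower, among them Mki67 (-1.14) and Cenpe (-0.84), and Birc5 (0.32) and Cks2 (0.015) highest. S phase genes had -0.29 (percentile 35.0), with Hells (-0.66) the 1 lower of 19, Mcm3 at -0.58, Dut at 0.23 and Rfc2 at 0.06.

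The remaining genes named by the rule in mononuclear phagocytes were lysozyme Lyz1 (43.8 to 161 CPM), metallothionein Mt2 (31.2 to 104 CPM), the apolipoprotein Apoc4 (38.4 to 119 CPM), the costimulatory ligand Tnfsf9 (16.7 to 45.2 CPM) and Ccdc152 (14.97 to 39.8 CPM) on the higher side. On the lower side were the proteoglycan Vcan (63.4 to 14.9 CPM), a gene of recruited monocytes, and Adgrl3 (54.4 to 5.10 CPM). Cmss1 (1411 to 191 CPM), Lars2 (927 to 147 CPM), Gphn (1438 to 272 CPM) and Camk1d (1499 to 473 CPM) were lower here and in all 6 classes examined. Fabp2 (59.6 to 0.162 CPM) stood at 16577 CPM in cluster 26 and the pancreatic protease Ctrb1 (34.98 CPM and 0 counts, at least 288-fold lower) at 51176 CPM in cluster 29 of the primary library.

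The fourth comparison covered T cells (1084 and 306 cells, of 5815498 and 572138 UMIs). In the chemoresistant library 7 of 19 cytotoxic genes were higher and 9 of 16 genes of naive and memory T cells lower, and the T cells of the 2 libraries lay in different T-cell clusters. T-cell cluster 5, led by haemoglobin genes, Ccl4, Ccl3, Ccl5, Gzmk and Havcr2, held 5 primary and 84 chemoresistant cells, and cluster 12, led by Gzma and haemoglobin genes, 10 and 47. Clusters 10 and 11 held 61 and 0 and 55 and 3 cells. Gzma, Cd7 and Itgae were among the leading genes of clusters 10, 11 and 12 alike. Cells with these leading genes thus lay in different clusters in the 2 libraries, and cluster 12 alone does not show a gain of them. Clusters 1 and 7, both with Igfbp4, Dapl1 and Lef1 among their leading genes, held 156 and 1 and 77 and 1 cells. The granzyme Gzmk (ENSMUSG00000042385) stood at 19.8 CPM (16.3 to 23.7) in the primary and 169.5 CPM (137 to 207) in the chemoresistant library, a 7.05-fold difference. The chemokines Ccl3 and Ccl4 went from 47.5 (42.02 to 53.4) to 304 (261 to 353) CPM and from 132 (123 to 142) to 706 (639 to 778) CPM, with 2267 and 1821 CPM in primary and 779 and 633 CPM in chemoresistant neutrophils. The inhibitory receptors Havcr2 and Lag3 went from 13.6 (10.8 to 16.9) to 75.2 (54.4 to 101) CPM and from 19.8 (16.3 to 23.7) to 71.7 (51.4 to 97.2) CPM. Satb1, a chromatin organiser of thymocytes and naive T cells, went from 678 (657 to 699) to 294 (251 to 342) CPM, and the IL-2 receptor chain Il2ra from 153 (143 to 163) to 20.97 (10.8 to 36.6) CPM.

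Of 19 cytotoxic genes 7 were higher and 1, Ifng (-0.84), lower, with a median of 0.51 (percentile 100) and Klrd1 at -0.37. Naive and memory genes had a median of -0.66 (percentile 0), with 9 of 16 lower, among them Satb1 and Cxcr5 (-0.96), and 0 higher, with Cd27 at 0.22. Exhaustion-associated genes had 0.25 (percentile 99.5), with 6 of 20 higher and 2 lower, Cd244a (-1.45) and Bhlhe40 (-0.75). Checkpoint genes had 0.094 (percentile 88.9), with 6 of 20 higher and 3 lower, among them Cd274 (-1.02) and Cd200r1 (-0.94). The regulatory T programme had 0.081 (percentile 87.1), with Il10 (1.59) and Ikzf4 (0.86) among 3 higher of 16 and Il2ra and Il1rl1 as the 2 lower. G2 and M genes had 0.52 (percentile 100), with 11 of 23 higher, led by Birc5 (1.53, from 153 and 49 counts) and Tpx2 (1.28, from 75 and 22 counts), and Kif23 (-0.32) and Smc4 (-0.44) lowest. The proliferation gene Mki67 went from 46.8 to 38.5 CPM, detected in 7.47% and 4.58% of cells, and T-cell cluster 16, with Mki67, Birc5 and Top2a among its leading genes, held 10 and 9 cells. S phase genes had 0.028 (percentile 74.0), with 4 of 20 higher, among them Pcna (0.70) and Chaf1b (0.68), and 2 lower, Mcm2 (-0.62) and Mcm7 (-0.84). Type I interferon genes had -0.40 (percentile 0.475), with 7 of 23 lower, among them Ifit3 (-1.17) and Oas3 (-0.92), and Xaf1 (0.54) and Ifi35 (0.39) highest.

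Immediate early and heat shock genes had a median of -0.64 in T cells (percentile 0), with 14 of 25 lower and Hspb1 (1.01) the 1 higher, with Hspe1 at 0.22. The inducible chaperone Hspa1a stood at 85.6 CPM and 0 counts, at least 16.3-fold lower, and Hspa1b went from 162 (151 to 172) to 10.5 (3.85 to 22.8) CPM. Frmd5, a leading gene of the regulatory T cluster, and Il1rl1, the receptor for IL-33, went from 44.9 (39.6 to 50.7) to 1.75 (0.0443 to 9.74) CPM and from 56.7 (50.8 to 63.2) to 3.50 (0.423 to 12.6) CPM, resting on 1 and 2 counts. Il1rl1 was a leading gene of the regulatory T cluster and of the type 2 innate lymphoid cluster (40 and 1 cells), and Il2ra was one of the latter and of T-cell cluster 4 (92 and 0 cells). The adhesion receptor Adgrg1 went from 5.67 (3.91 to 7.97) to 52.4 (35.4 to 74.9) CPM, with 185 and 89.01 CPM in tumour cells. Lgals7 (26.1 to 279.6 CPM), Nnmt (1.55 to 40.2 CPM), Smim1 (7.39 to 57.7 CPM) and Prcd (2.92 to 34.96 CPM) were higher in T cells while chemoresistant tumour cells held 2495, 260.0, 401 and 242 CPM. Fabp2, Ctrb1, Cela2a and Apoa1, products of gut and pancreas, had 77.6, 48.3, 38.2 and 32.3 CPM in primary T cells and 0 counts in chemoresistant ones, at least 14.8, 9.22, 7.28 and 6.17-fold lower. Clusters 26 and 29 of the primary library held 7779 CPM of Apoa1 and 34857 CPM of Cela2a. The median of all 9297 genes in T cells lay at -0.056. After thinning to 2000 UMIs per cell, which left 987 and 115 cells, the naive and memory median was -1.21 and the G2 and M median 1.30.

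The last comparison covered fibroblasts (390 and 464 cells), and it set clusters 27 and 32 of the primary library against cluster 20 of the chemoresistant library. Cluster 20 also carried 3 of 16 tumour epithelial markers, and its chromosome profile correlated at 0.758 with the tumour clusters. Host fibroblasts and tumour cells cannot be told apart for it, so the ratios below may set tumour cells against fibroblasts. Cluster 24 (232 and 47 cells), with 10 of 11 fibroblast markers, was set aside and is not included. Cluster 27, at a median of 1074.5 UMIs in the primary library, carried 5 of 11 macrophage markers beside 4 of 11 fibroblast markers. Inflammatory fibroblast genes were far lower in cluster 20, with a median log2 ratio of -3.83 (percentile 0) and 20 of 21 lower. The eosinophil chemokine Ccl11 stood at 349 CPM and 0 counts, at least 877-fold lower, Clec3b went from 546 (517 to 577) to 2.12 (1.21 to 3.45) CPM and the cytokine Il6 from 672 (639 to 706) to 21.4 (18.2 to 24.95) CPM, while the hyaluronan synthase Has2 (0.89) was the 1 higher and Cxcl1 stood at -0.93. Hypoxia and glycolysis genes had a median of 1.92 (percentile 100), with 28 of 31 higher, among them Ero1a (41.6 (33.7 to 50.7) to 931 (909.8 to 954) CPM) and carbonic anhydrase Car9 (0.857 (0.104 to 3.10) to 63.7 (58.2 to 69.7) CPM), and 3 lower, among them Adm (-5.81) and Pfkfb3 (-1.13).

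NF-kB genes had a median of -1.95 (percentile 0), with 20 of 23 lower, among them Icam1 (-4.55), Cxcl5 (2.39) the 1 higher and Lcn2 at 0.34. MHC class II genes, which macrophages also express, had -2.10 (percentile 0), with 10 of 11 lower, among them Cd74 (-3.18) and H2-Eb1 (-2.79), and H2-DMb1 (-0.49) and H2-Oa (-1.29) highest. MHC class I genes had -1.09 (percentile 0.0100), with 14 of 18 lower, among them H2-Q6 (-2.83) and H2-Q7 (-2.54), and Psme2 (0.15) and Psmb10 (-0.41) highest. Type I interferon genes had -0.37 (percentile 40.1), with 6 of 25 higher, led by Isg15 (1.61) and Ifi44 (1.55), and 10 lower, among them Ifi27l2a (-3.51) and Parp14 (-1.43). G2 and M genes had 1.19 (percentile 100), with 16 of 18 higher, among them Cenpa (2.00) and Birc5 (1.99), Kif11 at 0.098 and Mki67 at -0.35. S phase genes had 0.31 (percentile 99.92), with 7 of 18 higher, among them Dut (1.70) and Hells (1.04), and Rfc2 (-0.21) and Mcm6 (-0.53) lowest. Immediate early and heat shock genes had 0.27 (percentile 71.4), with Fosl1 (1.88) and Ier3 (1.04) among 11 higher of 26 and Jun (-1.36) and Zfp36 (-1.30) among 4 lower. Contractile and matrix genes had 0.12 (percentile 69.6), with 9 of 21 higher, led by Inhba (3.85) and Tnc (3.76), and 8 lower, among them Thbs2 (-3.38) and Col5a2 (-2.87). That median was -0.035 with doublets kept and -0.048 with the same doublet share removed from both libraries.

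By the rule for single genes, the T-cell costimulatory receptor Tnfrsf9 (2.14 to 217 CPM) was higher in cluster 20, and the matrix protein Svep1 (1022 to 3.19 CPM), glutathione peroxidase Gpx3 (1192 to 6.24 CPM) and the cGMP-dependent kinase Prkg1 (529.8 to 0.797 CPM) lower. Ndufa4l2 (6.43 to 771 CPM) and Spp1 (61.7 to 3377 CPM) were also taken by the rule, but both are among the 10 leading genes that set cluster 20 apart and so are no separate result. Median depth was 1676 and 14433.5 UMIs, and the median of all 9970 genes lay at -0.30. With doublets kept, the medians were -0.78 for MHC class II and -1.16 for NF-kB genes. As a mean over cells, the G2 and M median was 0.35 and the S phase median turned negative.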

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

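The single result here was found by a search over all clusters outside the compared classes, chosen after the data were seen, and no explanation was tested. Cluster 38, whose leading genes are those of complement-bearing macrophages (Saa3, Fcna, Vsig4, C1qa) and which carried all 8 markers of type 1 conventional dendritic cells and 10 of 11 of macrophages, held 42 cells of the chemoresistant library (0.323%, interval 0.233 to 0.436%) and 5 of the primary library (0.0399%, 0.0130 to 0.0931%). It drew attention because these cells enter no comparison of expression and their share lay above that in the primary library. Their median depth was 13842 UMIs in the chemoresistant and 14492 UMIs in the primary library, against 4099.5 and 5628 in all cells of these libraries. With doublets kept, a cluster with like leading genes and the same marker counts held 130 chemoresistant and 13 primary cells. Whether cluster 38 is what doublet removal left of such cells was not tested.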

How the results depend on the processing

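The tests with the same doublet share removed from both libraries, with cluster 20 counted as tumour, without tumour clusters 13 and 30 and with the mean over 6 shared tumour clusters were chosen after the results were seen, and the others were fixed in advance. No paired analysis was possible because each group is 1 library and no value comes from a test. Of 63 alternative values of the shares, 34 stayed within counting error, 23 moved in the same direction and 6 reversed. Of 141 values of the lists that lead each comparison, 71 stayed, 56 moved and 14 reversed, and of 407 values of the other lists 240 stayed, 154 moved and 13 reversed. The tumour share was higher in the chemoresistant library under all 7 alternatives (14.2 to 19.7 points), and the T-cell and neutrophil shares were lower under all 7 (-7.22 to -5.91 and -10.6 to -6.58). None of these alternatives loosened the limits on UMIs, genes or mitochondrial UMIs. The gene limit removed 287 primary and 1085 chemoresistant barcodes. Median depth was 2415.5 and 892.5 UMIs in neutrophils and 4879 and 1653.5 in T cells. The alternatives therefore cannot decide whether shallow cells of these classes were lost unequally. The 20% mitochondrial limit removed 10.3% of primary and 2.61% of chemoresistant barcodes. Whether the mitochondrial limit removed tumour cells unequally was not tested. In tumour cells the immediate early and heat shock median stayed between -1.66 and -0.84, NF-kB between -1.40 and -0.59 and hypoxia between 0.23 and 0.53 under all 13 alternatives. In T cells the cytotoxic median stayed between 0.38 and 0.74 under all 9. Of the 4 classes that were thinned, T cells lost the largest share of chemoresistant cells, since thinning left 115 of 306 chemoresistant cells against 987 of 1084 primary ones. Alternatives for endothelial expression were not run because the chemoresistant library held 7 such cells.

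The following differences in share (percentage points) and list medians (log2 ratio), all chemoresistant against primary, changed direction, and the cause was not tested. With shares taken outside the tumour class, the share differences were 0.870 (DC) and 2.30 (B lineage). With cluster 20 counted as tumour, the share difference was -3.06 (fibroblast), and the tumour medians -0.067 (p53 targets), -0.0084 (MHC class I), 0.38 (mesenchymal) and 0.032 (unfolded protein). With T subsets called from transcripts, the share differences were 6.19 (CD8 T among T) and -2.57 (regulatory T among T). With resolution 2.0, the share difference was 9.90 (CD8 T among T). With cells thinned to 2000 UMIs, the tumour medians were -0.096 (p53 targets) and 0.067 (mesenchymal), and the mononuclear phagocyte median 0.039 (immediate early). With doublets kept, the tumour median was -0.026 (p53 targets), the T cell median -0.048 (S phase), and the fibroblast median -0.035 (contractile). With the stricter filter on barcodes, the tumour median was -0.045 (p53 targets). With no filter on list members, the tumour medians were -0.051 (p53 targets) and -4.18e-05 (epithelial). With the same doublet share removed from both libraries, the tumour medians were -0.024 (p53 targets), 0.057 (type I interferon) and 0.010 (checkpoint), and the fibroblast median -0.048 (contractile). With the mean over the 6 shared tumour clusters, the tumour medians were -0.10 (p53 targets) and -0.21 (MHC class I). With the mean over cells scaled to 1 total, the tumour median was -0.046 (MHC class I), the mononuclear phagocyte median 0.046 (immediate early), and the fibroblast median -0.23 (S phase). With ratios centred on the median gene, the tumour median was 0.061 (unfolded protein), and the mononuclear phagocyte medians 0.0044 (MHC class II), 0.16 (immediate early), 0.12 (tissue remodelling) and 0.14 (classical activation).

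The following shares and leading lists of each comparison kept their direction but moved by more than their counting error, and again the cause was not tested. With the stricter filter on barcodes, the share differences were 18.4 (tumour), 9.27 (mononuclear phagocyte), -10.6 (neutrophil), -7.04 (T cell), -6.08 (B lineage), 1.77 (fibroblast) and -0.807 (endothelial), and the tumour median -1.08 (NF-kB). With doublets kept, the share differences were 17.9 (tumour), 4.31 (mononuclear phagocyte), -7.22 (T cell), -4.89 (B lineage) and 2.98 (fibroblast), the tumour medians 0.092 (MHC class I) and -0.73 (NF-kB), the mononuclear phagocyte median 0.22 (complement), and the T cell median -0.79 (naive and memory). With the class taken per cell from its highest marker score, the share differences were 14.2 (tumour), 4.26 (mononuclear phagocyte) and -0.779 (endothelial). With the same doublet share removed from both libraries, the share differences were 17.8 (tumour), -8.04 (neutrophil), -5.10 (B lineage), 1.17 (fibroblast) and -0.765 (endothelial), the tumour medians 0.15 (MHC class I), 0.38 (hypoxia) and -0.71 (NF-kB), and the mononuclear phagocyte medians -0.17 (MHC class II) and 0.21 (complement). With cluster 20 counted as tumour, the share difference was 19.7 (tumour), and the tumour medians 0.53 (hypoxia) and -1.08 (NF-kB). With shares taken outside the tumour class, the share differences were 14.9 (mononuclear phagocyte) and 1.37 (fibroblast). With ratios centred on the median gene, the tumour medians were 0.13 (p53 targets), -0.45 (G2 and M), -0.0040 (type I interferon), 0.18 (MHC class I), 0.43 (hypoxia) and -0.89 (NF-kB), the mononuclear phagocyte medians 0.30 (type I interferon) and 0.54 (complement), and the fibroblast medians 0.42 (contractile) and -3.53 (inflammatory). With a pseudocount of 1 CPM, the tumour medians were -0.77 (G2 and M) and -1.25 (NF-kB), and the fibroblast median -4.25 (inflammatory). With cells thinned to 2000 UMIs, the tumour medians were -0.70 (G2 and M), -0.39 (type I interferon), 0.23 (hypoxia) and -1.15 (NF-kB), the mononuclear phagocyte medians 0.13 (type I interferon), -0.11 (MHC class II) and 0.19 (complement), the T cell medians 0.74 (cytotoxic) and -1.21 (naive and memory), and the fibroblast medians 0.35 (contractile) and -3.56 (inflammatory). With cells with Mki67, Top2a or Cdk1 counts left out, the tumour medians were -0.20 (G2 and M), 0.23 (MHC class I), 0.36 (hypoxia) and -0.96 (NF-kB). With the mean over the 6 shared tumour clusters, the tumour medians were -0.21 (G2 and M), -0.057 (type I interferon) and -0.59 (NF-kB). With the mean over cells scaled to 1 total, the tumour median was -0.40 (type I interferon), the mononuclear phagocyte medians -0.088 (MHC class II) and 0.19 (complement), the T cell median -0.44 (naive and memory), and the fibroblast medians 0.41 (contractile) and -3.20 (inflammatory). With 5% free RNA subtracted, the tumour medians were 0.10 (MHC class I) and -1.40 (NF-kB), the mononuclear phagocyte median -0.17 (MHC class II), and the fibroblast median -4.18 (inflammatory). With no filter on list members, the tumour medians were 0.35 (hypoxia) and -0.60 (NF-kB), and the mononuclear phagocyte median 0.15 (type I interferon).

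The 154 moved values of the other lists are given as a count, apart from these tumour medians, whose cause was not tested either. Without a filter on list members, stem-associated genes stood at -0.12, mesenchymal genes at -0.011 and platinum and drug transport genes at 0.0053. MHC class II genes stood at 0.26 after thinning, 0.17 as a mean over cells and 0.077 as a mean over the 6 shared clusters, where NRF2 targets stood at 0.064. Checkpoint genes stood at -0.067 with 5% free RNA subtracted.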

Other observations

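Every test in this part was chosen after the result was seen, except thinning to 2000 UMIs, which was fixed in advance as an alternative. Tumour cells of both libraries had a like profile of expression over chromosomes. Against leukocyte clusters, genes on chromosome 15 had a median log2 ratio of 0.65 in primary and 0.66 in chemoresistant tumour cells, and genes on chromosome 19 had 0.63 in each. Chromosome 12 stood at -0.59 and -0.49 and chromosome 18 at -0.35 and -0.28. Primary endothelial cells stood at 0.049 and -0.056 on chromosomes 15 and 19, and fibroblast cluster 32 at 0.041 and -0.066. Over the 20 chromosomes the profiles of the tumour class in the 2 libraries correlated at 0.929, a value over chromosomes and not over samples. Tumour cluster 8, the one with most primary tumour cells, had 0.63 and 0.64 on chromosomes 15 and 19, and cluster 5, the one with most chemoresistant tumour cells, 0.65 and 0.69.

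A few genes differed between the libraries in every class examined. Lars2, which encodes the mitochondrial leucine tRNA synthetase, Cmss1, the synaptic scaffold gene Gphn and the kinase gene Camk1d were lower in the chemoresistant library in all 6 classes. The log2 ratios ran from -2.71 to -1.34 for Lars2, from -3.02 to -1.69 for Cmss1, from -2.38 to -1.13 for Gphn and from -2.74 to -0.75 for Camk1d. In dendritic cells Cmss1 went from 1653 to 199 CPM, and in neutrophils Lars2 went from 1115 to 317 CPM.

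Genes of chromosomes 8 and 10 were lower in chemoresistant tumour cells. After centring, their median log2 ratios were -0.24 (364 genes) and -0.21 (362 genes), below all 10000 matched random lists. Chromosomes 2, 4, 7 and 9 lay above all of these lists at smaller medians (0.092 to 0.14). Most other chromosomes also lay near the ends of the lists. The lists therefore do not set apart chromosomes 8 and 10, which had the lowest medians of all chromosomes. A difference between libraries that is not tied to tumour cells would show in other cells, yet the median over 5 other classes was -0.019 for chromosome 8 and -0.020 for chromosome 10. A different mix of tumour clusters is argued against by the mean over 6 shared clusters, -0.24 and -0.20. Medians over 364 and 362 genes move little with a few large changes. Of the genes of both chromosomes, 74.8% lay below the median of all genes, which follows from the low medians and is no separate test. A loss of copies on both chromosomes in chemoresistant tumour cells may account for their lower genes. That is a hypothesis from expression alone that a measurement of DNA copy number would decide. Treatment or other differences between the pooled tumours were not tested as its origin.

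Immediate early and heat shock genes were lower in chemoresistant tumour cells (median -1.49). The mean over 6 shared clusters was -0.84, which argues against a different cluster mix as the whole cause but leaves room for a part. The median after thinning was -1.23. Thinning leaves the expected proportions within each cell unchanged, so it cannot decide whether depth had a part. Handling of the suspension that differed between the libraries stays open: the median over 5 other classes was -0.64, although mononuclear phagocytes stood at -0.080. With 1 suspension per group, handling and treatment cannot be told apart for these genes, and an effect of cisplatin stays untested.

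The collagen-rich cluster 20 (459 chemoresistant and 2 primary cells) is a fibroblast cluster by its markers. With doublets kept, a cluster with like leading genes held 636 chemoresistant cells. In cluster 20 itself, Krt18 and Krt19 reached 8.04% of their level in the tumour class. That argues against doublets of a tumour cell and a fibroblast among the cells left. Krt8 and Krt19 still counted among the enriched markers of cluster 20. Its chromosome profile correlated at 0.334 with fibroblast cluster 32, at 0.574 with the chemoresistant and at 0.672 with the primary tumour class, and at 0.758 with the mean over tumour clusters with both libraries pooled, while cluster 32 stood at 0.017 against the chemoresistant tumour class. Its chromosomes 15 and 19 lay at 0.43 and 0.21, between tumour and fibroblast values, whereas chromosomes 8 and 10 lay at 0.32 and 0.084, apart from the chemoresistant tumour class at -0.18 and -0.26. In addition, fibroblast cluster 27 correlated with the chemoresistant tumour class although its chromosomes 15 and 19 lay at 0.033 and 0.0056. Host fibroblasts and tumour cells in a collagen-rich state cannot be told apart for this cluster, since its correlation was higher with tumour cells than with cluster 32, but chromosomes 8 and 10 went the other way and cluster 27 reached 0.514.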
